A study of Rattus norvegicus with 4 samples.

How the data were processed

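Spatial gene expression was measured with the 10x Visium assay on 10 µm frozen kidney sections of Sprague-Dawley rats. There were 4 sections, 1 for each of 4 groups. The group PAN had received puromycin aminonucleoside, a toxin of podocytes, and was examined 5 months after the injection and 6 weeks after the treatment period. The group PAN_LS-FMD had the same injection and the same times and had gone through 6 cycles of a low-salt fasting-mimicking diet (LS-FMD). The group healthy had no treatment, and the group healthy_LS-FMD was taken after 1 cycle of the diet and 72 h of refeeding. Each section was a single tissue piece from its group, so the number of replicates was 1 throughout, and no p-value or standard error between animals could be computed.

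The deposited matrices hold counts, that is whole-number UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) per gene and spot, with no normalisation. A spot is a small region of the slide that can hold several cells of different types. Per the file headers, the authors made the count matrix of the healthy section with Space Ranger 2.0.1 and those of the other 3 sections with Space Ranger 1.2.1, so the 3 comparisons with the healthy section carried this difference of version. The genome build and the annotation were not given in the sources used here. Spot coordinates and images were not used here. All 4 matrices had the same 32402 features, each an Ensembl gene identifier with a symbol. The deposited spots were those over tissue, 2729 in the PAN section, 2869 in the healthy section, 2190 in the PAN_LS-FMD section and 2595 in the healthy_LS-FMD section. Spots under 500 UMIs were left out, which removed 5, 3, 3 and 2 of them. No doublet caller and no estimate of cell-type makeup was run, since a spot is not a cell.

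Each section was clustered alone. Counts were scaled to 10000 per spot and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and a graph of 15 neighbours was divided by the Leiden method at resolution 1. A cluster was given to a zone (cortex, outer stripe, medulla or blood-rich) by the marker list with the highest score. The score was the mean of log2(CPM + 10) over the genes of a list, centred on the mean of the clusters of that section, where CPM is UMIs scaled to a total of 1000000. Podocyte, proximal tubule S1 and S2, and distal convoluted and connecting tubule markers stood for cortex. Proximal tubule S3 markers stood for outer stripe, thick ascending limb, principal cell and inner medulla markers for medulla, and red blood cell genes for blood-rich regions. The markers were fixed before the data were examined, and this scoring rule was set afterwards.

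For each comparison, UMIs were summed over the cortical spots of each section and divided by all UMIs in those spots. The cortical sums were 11318470 UMIs in the PAN section, 18218378 in the healthy section, 14379053 in the PAN_LS-FMD section and 8847874 in the healthy_LS-FMD section. A count of 3 in these sums was worth 0.265, 0.165, 0.209 and 0.339 CPM in the same order, which was the floor for genes with no UMIs. Fold values have exact 95% intervals of 2 Poisson counts, levels have exact Poisson intervals, and shares have exact Clopper-Pearson intervals. All of these cover counting error only and say nothing of the spread between animals. Where a gene had 0 UMIs in a section, the fold was set against a floor of 3 counts over the cortical spots of that section and is given as "at least". The same sums over all spots gave the whole-section values.

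The 4 comparisons, 42 gene lists and the rule for named genes were fixed before the data were examined. Named genes were the 10 with the highest and the 10 with the lowest fold per comparison, among genes with at least 200 UMIs over the cortical spots of both sections and a whole-section fold of at least 1.5 in the same direction. Mitochondrially encoded, ribosomal protein, haemoglobin and provisional or pseudogene symbols were left out. Nphs1, Wt1, Synpo, Podxl, Pax2, Six2, Havcr1, Lcn2, Spp1 and Col1a1 were named throughout, and sex-linked genes served as a check of the animals. Some genes that these rules take are not reported here. A list member counted as measured at 20 UMIs over both sections, as higher or lower at a 1.5-fold difference whose counting interval excluded 1, and could be an example at 50 UMIs, with up to 4 examples per list by size. Beside its count, each list has the median log2 fold of its measured members and the percentile of that median among 10000 random lists of the same size and like expression, drawn for each member from the 100 genes nearest in expression. A list was said to be higher or lower when the counting interval of its median (from 1000 Poisson draws) excluded 0 and its percentile was above 97.5 or below 2.5. That rule was set after the data had been examined, and it describes these sections only.

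The lists held 502 genes, of which 473 were found by symbol and 9 by an older symbol of the same gene (Cyr61 for Ccn1, for example). The other 20 had no row under their symbol, among them Pecam1, Egf, Klk1 and Ace, and with them the whole list of nuclear-retained RNAs (Malat1, Neat1, Meg3), which was therefore not analysed here. Of the urothelium list too few UMIs were present to measure any member. Apart from the podocyte marker sets, 25 genes stood in more than 1 list. For the main injury list this was 3 of 26 genes and for the podocyte list 2 of 22, while 6 of 8 principal cell genes and 5 of 11 gluconeogenesis genes were shared. Where a symbol in a list belonged to several identifiers, the identifier with most UMIs was used. Genes named by size are rows of a single identifier.

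Glomerular spots were selected among spots thinned at random to 3000 UMIs, so that depth did not set their number. Spots with fewer UMIs were left out, 117 in the PAN section, 3 in the healthy section, 7 in the PAN_LS-FMD section and 42 in the healthy_LS-FMD section. Of these 44, 2, 1 and 11 were cortical. A cortical spot with at least 2 UMIs from podocyte marker set A (Ptpro, Tcf21, Thsd7a and Clic5 among them) was counted as glomerular, and set B (Nphs1, Synpo, Wt1, Cdkn1c, Podxl) was measured in these spots. The same share among spots outside cortex is given as background. The log2 folds of the diet contrast in injected rats were also correlated across genes with those in rats without injection.

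The alternatives were median-of-ratios size factors, totals without mitochondrially encoded genes or without the 20 most abundant genes, all deposited spots, a minimum of 2000 UMIs per spot, all spots of the section, clusters of the 4 sections together, a marker score per spot, resolutions of 0.5 and 2, thinning of spots to 3000 UMIs with shallower spots left out, cortical spots without glomerular spots, a minimum of 100 UMIs or none for list members, a 2-fold threshold, and a minimum of 3 UMIs, selection on set B or no thinning for glomerular spots. After the data had been examined, 4 more were added: the healthy_LS-FMD section as the reference, the PAN cortex without its matrix-rich cluster, the total without haemoglobin genes, and the cortex without clusters that had Cyp24a1 among their 10 leading genes.

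The steps were tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold in Poisson draws from the real cortical profile. Of the 2-fold changes, 100% were found for PAN against healthy, 100% for PAN_LS-FMD against PAN, 99% for PAN_LS-FMD against healthy and 99% for healthy_LS-FMD against healthy, and of the 4-fold changes 100% in each. Among the genes left as they were, 0.0235%, 0.0477%, 0.0241% and 0.0125% passed the same size rule. A simulated list of 20 genes, all raised 4-fold, came out at percentile 100 in all 4, and a list left as it was at 11.3, 40.2, 70.2 and 24.0. Lists with smaller shifts were not simulated. The simulation holds counting error only.

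The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.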

Results

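RNA was captured on Visium spots from 4 rat kidney sections, 1 each from the groups PAN, healthy, PAN_LS-FMD and healthy_LS-FMD. PAN stands for puromycin aminonucleoside, a podocyte toxin used to produce nephrotic kidney disease in rats, and LS-FMD for a low-salt fasting-mimicking diet. The sections held 24925280, 58569311, 34966981 and 25331233 UMIs in that order, with a median of 8472, 19519, 14939 and 8818 UMIs and of 3478, 4550, 4243 and 3406 genes per spot. Mitochondrially encoded RNA made up 3.11, 4.94, 3.46 and 5.27% of UMIs and haemoglobin RNA 0.161, 1.59, 0.196 and 0.234%. With 1 section per group there were no replicates and no tests, and each interval given is a 95% interval of counting error. A difference between groups is therefore a difference between these sections, and it could not be compared with the spread between animals. The Y-linked genes Eif2s3y (2904, 4030, 2744 and 2795 UMIs) and Kdm5d (655, 691, 526 and 511 UMIs) were present in all 4 sections.

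Spots of proximal S1 and S2, distal convoluted tubule and podocyte regions were pooled as cortical spots. They made up 44.4% (42.5 to 46.3) of the spots in the PAN section, 35.5% (33.8 to 37.3) in the healthy section, 48.7% (46.6 to 50.8) in the PAN_LS-FMD section and 37.1% (35.2 to 39.0) in the healthy_LS-FMD section. Outer stripe spots, assigned by S3 markers, made up 27.8, 37.6, 27.1 and 22.8%, and medullary spots 20.9, 20.3, 20.3 and 35.7%. Of the 758 outer stripe spots in the PAN section, 293 belonged to a region led by Serpine2, Pla2g2a and Alx1, in which the S3 score (0.22) was below those of injury (0.29) and matrix genes (0.26). The blood-rich remainder was 6.83, 6.56, 3.84 and 4.47%. At the coarser resolution, and when the sections were clustered together, no PAN_LS-FMD region was assigned to medulla. A region led by podocyte genes (Nphs1, Clic3, Wt1) was found in each section, with 32 spots in the PAN section, 120 in the healthy section, 105 in the PAN_LS-FMD section and 59 in the healthy_LS-FMD section. The PAN cortex also had a region of 392 spots, 32.4% of its cortical spots, that was led by the matrix and wound genes Lum, Postn, Ltbp2, Cyr61 and Tnc together with Car3 and Ankrd1. This region was assigned to cortex by a distal convoluted and connecting tubule score of 0.23, below its scores of matrix (0.78) and injury genes (0.35). The region with Havcr1 among its 10 leading genes had 130 spots and was in the PAN section. Regions with the vitamin D enzyme gene Cyp24a1 among their 10 leading genes fell into different zones. They had 255 outer stripe and 162 medullary spots in the healthy section, 220 cortical and 129 outer stripe spots in the PAN_LS-FMD section and 216 cortical spots in the healthy_LS-FMD section, and the PAN section had none. In the healthy_LS-FMD section they made up 22.5% of cortical spots and 37.1% of cortical UMIs, so the zones compared below did not hold the same regions in every section.

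The first comparison, PAN against healthy, asked what distinguished the kidney months after the podocyte toxin. In cortical spots of the PAN section, RNA of tubular injury, matrix and immune genes was many times higher than in the healthy section, and RNA of podocytes and of most tubule segments was lower. Levels are given in CPM, that is UMIs scaled to a total of 1000000. Spp1 (osteopontin, a secreted glycoprotein of injured tubules) stood at 19022 CPM against 224, a fold of 84.8 (82.2 to 87.5). Havcr1 (KIM-1, a membrane protein of injured proximal tubule) stood at 256 against 4.17, a fold of 61.5 (49.0 to 78.3). Lcn2 (lipocalin 2, released in tubular injury) stood at 240 against 10.9, a fold of 22.0 (19.1 to 25.5). Nphs1 (nephrin, of the podocyte filtration barrier) and Wt1 (a transcription factor of podocytes) stood at 17.5 and 10.8 CPM against 40.0 and 22.0. All genes together had a median log2 fold of 0.40 in this comparison, and of -0.05 with size factors by median of ratios. List medians are therefore set against random lists of like expression.

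Of 24 measured tubular injury genes, 21 were higher, 1 was lower and 2 did not pass the 1.5-fold rule. Their median log2 fold was 2.18 (2.03 to 2.32) against -0.08 to 0.58 for the central 95% of random lists. Of 26 matrix and fibrosis genes, 25 were higher and 1 did not pass, with a median of 2.70 (2.57 to 2.96). Examples were Postn (periostin), Lum (lumican, 21.4-fold) and Cyr61 (11.7-fold), and Col1a1 of type I collagen stood at 405 against 43.9 CPM. All 20 macrophage and MHC class II genes were higher, with a median of 2.54. The furthest apart were Mrc1 (the mannose receptor, 15-fold), RT1-Bb (12.1-fold), C1qb (8.28-fold) and RT1-Db1 (8.15-fold). RT1-Bb was low in the healthy section (3.81 CPM over all spots) and higher in the PAN_LS-FMD (110) and healthy_LS-FMD sections (125) than in the PAN section (49.3). The 8 measured T and NK cell genes were also all higher (median 2.26, Cd3e 9.21-fold). So were the 6 B and plasma cell genes (median 4.27, 3.79 to 4.77), with Ighm 43.3-fold, Igkc 30.9-fold, Cd79a 23.8-fold and Cd79b 15.6-fold. Complement genes were higher in 9 of 10 (median 2.26, Cfd 12.7-fold, Cfi 8.66-fold, C3 4.92-fold) and interferon response genes in 17 of 18 (median 1.41, Mx1 5.06-fold). Cell cycle genes were higher in 15 of 16 (median 2.37, Ccna2 10.2-fold, Mki67 7.90-fold), and mesangial and smooth muscle genes in 7 of 10 (median 1.55, Tagln 4.42-fold, Cnn1 4.0-fold). Immediate early genes (8 of 9 higher, median 1.18, Egr1 13.1-fold) and heat shock genes (5 of 8, median 0.92, Hspa1b 5.52-fold) also lay above random lists. The same was so for stress genes of the endoplasmic reticulum and amino acids (9 of 16 higher and 2 lower, median 0.85, Atf3 6.90-fold) and parietal epithelial genes (5 of 6 higher and 1 lower, median 1.03, Cd44 7.86-fold). Over all spots of the section the medians were 2.15 for injury, 2.58 for matrix, 2.59 for macrophage and 4.20 for B and plasma cell genes.

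Podocyte genes were higher in 3, lower in 10 and neither in 5 of 18 measured, with a median of -0.70 (-0.78 to -0.54) against -0.01 to 0.74 for random lists. Examples were Ddn (dendrin, 4.41-fold lower), Sema3g (3.19-fold lower) and Robo2 (2.41-fold higher). Podocyte marker sets A and B had medians of -0.70 and -1.0, with Nphs1 2.29-fold, Wt1 2.04-fold and Podxl 1.97-fold lower. Over all spots of the section the podocyte median was -0.16, beside a median of all genes of 0.45, and in cortical spots without the glomerular ones it was -0.0091. It was -0.36 when the sections were clustered together and -1.14 by median of ratios. The outer stripe and medullary spots had podocyte medians of 0.41 and 0.47. Nphs1 was nonetheless lower in the PAN section in both zones, at 2.39 against 4.96 and 2.36 against 6.30 CPM, from 17 and 11 UMIs there. Wt1 was lower in outer stripe (1.27 against 1.96) and higher in medulla (3.44 against 2.13). Podxl was higher in outer stripe (35.8 against 33.8) and lower in medulla (47.9 against 55.0). Proximal tubule S1 and S2 genes were lower in 9 of 15 and higher in 1 (median -0.77, Miox 3.45-fold lower, Slc2a2 2.87-fold higher, Pck1 2.86-fold lower), and S3 genes were lower in 4 of 5 (median -1.46). With the healthy_LS-FMD section as the reference the S1 and S2 median was 0.28, the opposite direction. Thick ascending limb genes were lower in 5 of 8 (median -0.83, Kcnj1 3.17-fold, Umod 2.03-fold), and distal convoluted and connecting tubule genes in 2 of 3 with 1 higher (median -1.39, Calb1 3.99-fold lower). Lower values were also found for principal cell genes (6 of 8, median -1.06, Aqp3 4.01-fold) and intercalated cell genes (6 of 6, median -1.34). Over the whole section these last groups lay closer to 0, with medians of -0.23 for thick ascending limb, -1.03 for distal tubule, -0.26 for principal cells and -0.37 for intercalated cells. In medullary spots the thick ascending limb median was 0.22, the opposite direction.

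Metabolic genes were mostly lower in the PAN cortex. This held for 10 of 15 nuclear genes of oxidative phosphorylation (median -0.76, Atp5a1 2.33-fold) and for 13 of 24 genes of fatty acid oxidation and ketogenesis, of which 2 were higher (median -0.65, Acaa2 4.30-fold and Ehhadh 3.86-fold lower, Plin2 4.20-fold higher). It also held for 6 of 9 gluconeogenesis genes, with 1 higher (median -1.03), and for 10 of 17 genes of sodium transport and its hormones (median -0.62), whose whole-section median was -0.01 and whose medians in outer stripe and medullary spots were 0.19 and 0.23. Red blood cell genes (5 of 5, median -3.42) and adipocyte genes (3 of 3, median -1.08) were lower. Since red blood cell genes also marked the blood-rich spots taken out of cortex, their cortical medians in every comparison depend on that rule. The nephron progenitor list (median 0.60, Meox1 11.5-fold higher, Cited1 10.6-fold lower) and the endothelial list (-0.07, Emcn 2.34-fold lower) did not meet the rule for lists. Neither did the antioxidant list (-0.46, Gclc 6.21-fold lower, Hmox1 6.12-fold higher), nor those of inner medulla (0.08), sterol synthesis (0.24), insulin and IGF (0.12), autophagy (0.08), clock (0.15), glucocorticoid (0.38), hypoxia (-0.01) and adrenal genes (1.78).

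Among the genes with the highest fold, Il24 (a cytokine, 811-fold, 145 to 32105), Aoc1 (a diamine oxidase, 588-fold, 105 to 23268) and Postn (130-fold, 44.1 to 637) rested on 1, 1 and 3 UMIs in the healthy section. Pnoc, the precursor of nociceptin, had none there and was at least 127-fold higher. The others were Mcpt1 (a mast cell protease, 218-fold), Cdkn2b (a cell cycle inhibitor, 56.6-fold), Cthrc1 (54.2-fold) and Col8a1 (a collagen, 47.8-fold), with Spp1 and Havcr1. Those with the lowest were Klk1c3 (a kallikrein, 139-fold lower), Cyp2c11 (a cytochrome P450, 71.7-fold), Gal (galanin, 60.8-fold) and Dusp15 (56.5-fold, 19.1 to 276, from 3 UMIs in the PAN section). They were followed by Cyp4a2 (18.8-fold), Slc7a13 (an amino acid transporter of S3, 17.8-fold), Kap (an androgen-regulated proximal tubule protein, 17.5-fold), Ros1 (17.5-fold), Iqch (16.6-fold) and Slco1a1 (an organic anion transporter, 15.3-fold). Klk1c3 and Cyp4a2 are symbols of more than 1 identifier. The more abundant Cyp4a2 identifier stood at 5087 against 7230 CPM.

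**Figure D1:**
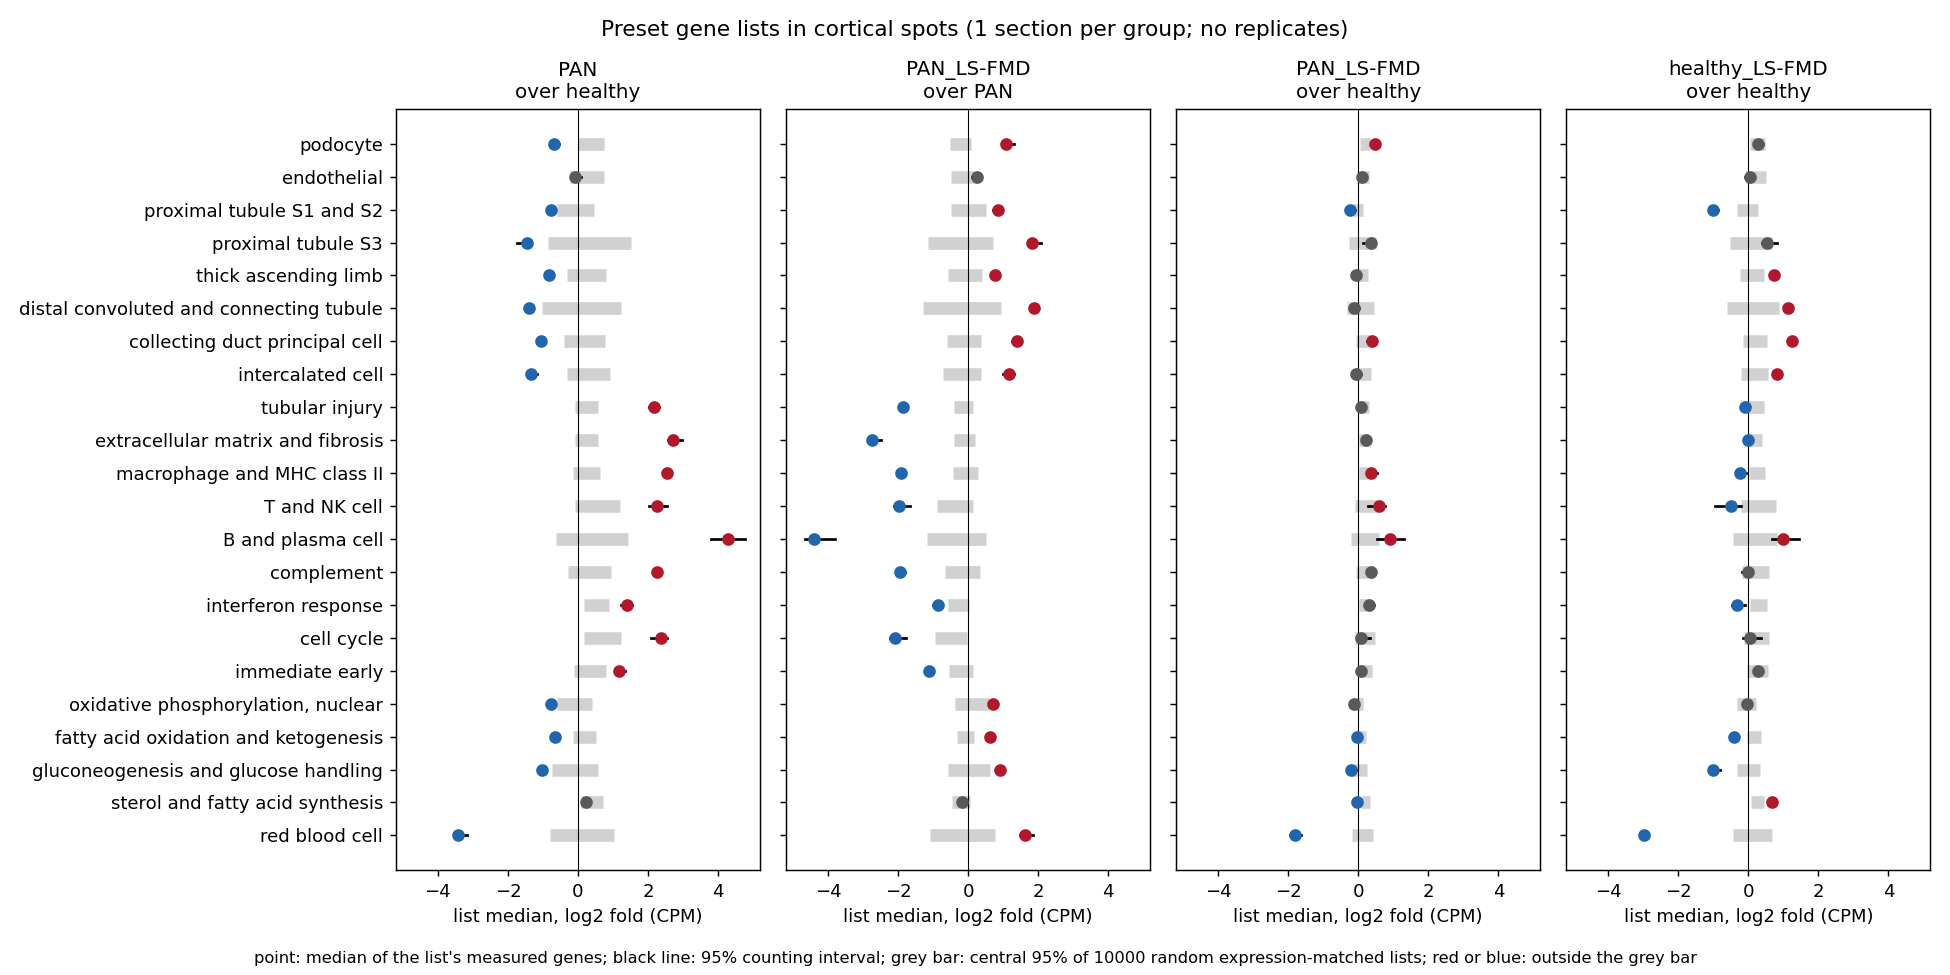
Median log2 fold of each gene list (vertical axis) in cortical spots for the 4 comparisons (panels), with the 95% counting interval as a black line and the central 95% of 10000 random lists of like expression as a grey bar; points in red and blue lie above and below that bar. The tubular injury list stood at 2.18 for PAN against healthy, -1.86 for PAN_LS-FMD against PAN, 0.08 for PAN_LS-FMD against healthy and -0.10 for healthy_LS-FMD against healthy.

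The second comparison, PAN_LS-FMD against PAN, asked how the injected kidney differed after 6 cycles of the diet. Cortical spots of the PAN_LS-FMD section held far less injury, matrix and immune RNA than those of the PAN section, and more podocyte and tubule RNA. Havcr1 was 90.0-fold lower (66.1 to 126), Spp1 63.6-fold lower (61.7 to 65.6) and Lcn2 18.3-fold lower (15.8 to 21.3), at 2.85, 299 and 13.1 CPM. Nphs1 was 4.0-fold higher (3.43 to 4.68), Wt1 3.52-fold and Podxl (podocalyxin, of the podocyte surface) 2.53-fold. All genes had a median log2 fold of -0.20, and of 0.05 by median of ratios.

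Of the tubular injury genes, 21 of 24 were lower and 1 was higher (median -1.86, -1.99 to -1.78, against -0.41 to 0.13 for random lists), with Fgb 11.3-fold lower besides the 3 above. Matrix genes were lower in 25 of 26 (median -2.74, Lum 62.8-fold, Vcan 13.3-fold), and Col1a1 stood at 39.9 CPM. Macrophage and MHC class II genes were lower in 19 of 20 (median -1.91, Mrc1 10.6-fold, Ctss 5.75-fold, RT1-Da 5.38-fold). RT1-Bb was the member that was higher. T and NK cell genes were lower in 8 of 8 (median -1.96, Cd3e 5.99-fold) and B and plasma cell genes in 5 of 6 (median -4.40, Cd79b 40.3-fold, Igkc 11-fold). Cd79a (47.0-fold, 12.6 to 395) rested on 2 UMIs in the PAN_LS-FMD section. Lower medians were also found for complement (9 of 10 lower, -1.94, Cfi 15.7-fold), interferon response (15 of 18, -0.87, Cxcl9 6.43-fold) and cell cycle genes (14 of 16, -2.08, Cenpf 16.5-fold, Top2a 7.62-fold). The same was so for immediate early genes (7 of 9, -1.11, Egr1 9.83-fold) and for mesangial and smooth muscle genes (6 of 10 lower and 1 higher, -1.34, Cnn1 10.3-fold lower). Over all spots of the section the medians were -2.09 for injury, -2.84 for matrix, -1.98 for macrophage and -4.28 for B and plasma cell genes.

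Podocyte genes were higher in 11 of 17 and lower in none (median 1.09, 0.98 to 1.32, against -0.53 to 0.08), led by Ddn (6.95-fold), and marker sets A and B had medians of 1.14 and 1.58. The whole-section median was 0.58, and outer stripe and medullary spots had podocyte medians of -0.31 and -0.37. Tubule lists lay above random lists from the proximal to the collecting segments. They began with proximal tubule S1 and S2 (9 of 15 higher and 2 lower, median 0.85, Pck1 3.12-fold higher, Slc2a2 2.88-fold lower) and S3 (5 of 5, 1.83). Next came thick ascending limb (5 of 8 higher and 1 lower, 0.75, Kcnj1 3.26-fold, Umod 2.66-fold) and distal convoluted and connecting tubule (2 of 3 higher and 1 lower, 1.87, Slc12a3 3.92-fold higher, Trpv5 2.07-fold lower). Principal cell genes (8 of 8, 1.39, Aqp2 2.81-fold) and intercalated cell genes (6 of 6, 1.16, Slc4a1 3.10-fold) followed. Over all spots the medians of thick ascending limb (0.02), principal cell (0.51) and intercalated cell genes (0.29) were smaller. In medullary spots they were -0.74, -0.08 and -0.77. Inner medulla genes (4 of 7 higher and 3 lower) had a median of 0.63 in cortical spots, -0.16 in medullary spots and -0.50 over the section. Oxidative phosphorylation genes were higher in 8 of 15 (0.70, Cycs 2.23-fold). Fatty acid oxidation (14 of 24 higher and 2 lower, 0.64, Ehhadh 3.78-fold higher, Plin2 3.01-fold lower) and gluconeogenesis lists (6 of 9 higher and 2 lower, 0.90, G6pc 2.51-fold higher) were higher. So were genes of sodium transport and its hormones (11 of 17 higher and 1 lower, 1.08), hypoxia (4 of 11 higher and 2 lower, 0.42), red blood cells (5 of 5, 1.61) and adipocytes (3 of 3, 0.68). In outer stripe and medullary spots the medians were -0.05 and -0.25 for sodium transport and -0.50 and -0.44 for hypoxia.

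The nephron progenitor (median -0.15, Foxd1 4.87-fold higher, Meox1 4.83-fold lower), parietal epithelial (-0.62, Cd44 8.86-fold lower) and endothelial lists (0.27, Emcn 1.94-fold higher) did not meet the rule for lists. Neither did the antioxidant list (0.48, Gclc 8.40-fold higher), nor those of sterol synthesis (-0.18), endoplasmic reticulum stress (-0.24), insulin and IGF (-0.21), autophagy (-0.09), heat shock (-0.21), clock (0.13), glucocorticoid (-0.25) and adrenal genes (-0.70). The genes with the highest fold were Klk1c3 (65.5-fold), Dusp15 (58.2-fold, 19.7 to 285, from 3 UMIs in the PAN section), and Pgam2 (a glycolytic enzyme, 25.6-fold). They were followed by the amino acid transporters Slc7a13 (23.2-fold) and Slc7a12 (18.9-fold), Kap (17.7-fold), Iqch (14.8-fold), Slco1a6 (13.3-fold), Gng13 (12.0-fold) and Dnase1 (11.3-fold). Those with the lowest included Mcpt1, the immunoglobulin heavy chain Igh-6 and Aoc1, which had no UMIs in the PAN_LS-FMD cortex and were at least 287-fold, 222-fold and 155-fold lower. Il24 (320-fold lower, 88.2 to 2651) and Postn (154-fold lower, 42.3 to 1282) had 2 UMIs each there. Cthrc1 (96.2-fold), Cyp1b1 (a cytochrome P450, 72.8-fold) and Car3 (a carbonic anhydrase, 63.5-fold) completed them with Havcr1 and Spp1.

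**Figure D2:**
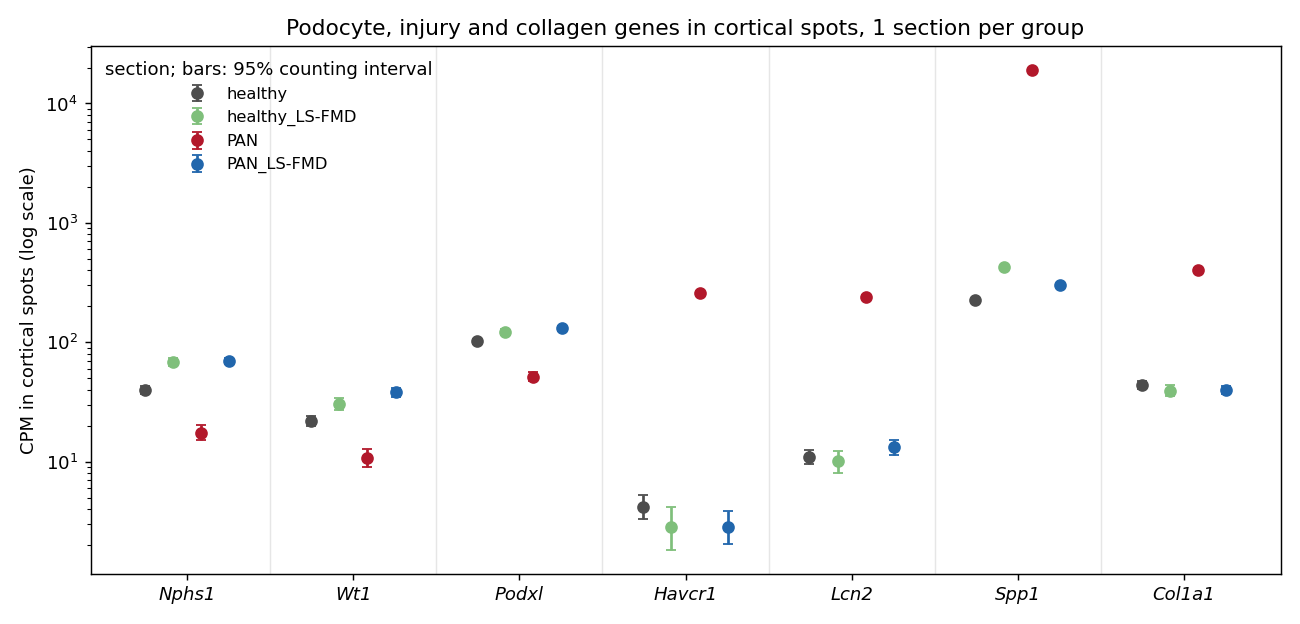
CPM (vertical axis, log scale) of 7 genes in the cortical spots of the 4 sections, with 95% counting intervals as bars. Spp1 (19022), Havcr1 (256), Lcn2 (240) and Col1a1 (405) were highest in the PAN section, where Nphs1 (17.5), Wt1 (10.8) and Podxl (51.6) were lowest.

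The third comparison, PAN_LS-FMD against healthy, asked how far the injected and dieted kidney lay from the untreated one. Injury and matrix genes of the cortex lay near the level of the healthy section, while podocyte, stress and some immune genes were higher. Nphs1 was 1.75-fold higher (1.59 to 1.93) and Wt1 1.73-fold, while Podxl (1.29-fold) did not pass the size rule. Havcr1 stood at 2.85 (2.05 to 3.87) against 4.17 (3.29 to 5.22) CPM, Lcn2 at 13.1 against 10.9, Spp1 at 299 against 224 and Col1a1 at 39.9 against 43.9. Spp1 had the opposite direction over the whole section, with a log2 fold of -0.56. All genes had a median log2 fold of 0.18, and of -0.01 by median of ratios.

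Tubular injury genes were higher in 3 of 23, lower in 1 and neither in 19, with a median of 0.08 (-0.03 to 0.15) inside the range of random lists (0.01 to 0.31). The median was -0.12 by median of ratios and -0.23 over the section. Matrix genes were higher in 3 of 24 and lower in 1 (median 0.22; Cyr61 1.56-fold higher). Podocyte genes were higher in 6 of 18 and lower in none, with a median of 0.49 (0.42 to 0.57) against 0.04 to 0.34, and the median was 0.19 against the healthy_LS-FMD section, 0.29 by median of ratios and 0.84 when the sections were clustered together. Marker sets A and B had medians of 0.43 and 0.80, and Cdkn1c was 1.79-fold and Robo2 1.62-fold higher. Macrophage and MHC class II genes were higher in 7 of 19 (median 0.35, C1qa 2.13-fold, C1qb 2.11-fold). T and NK cell genes were higher in 4 of 8 with 1 lower (0.59, Cd3d 1.85-fold higher, Ccl5 1.56-fold lower), and B and plasma cell genes in 2 of 4 with 1 lower (0.91, Ighm 4.85-fold, Igkc 2.80-fold). The T and NK cell median was -0.13 in both outer stripe and medullary spots, with 0 members higher and 1 lower in each. The B and plasma cell median was -0.56 over the section and -0.09 against the healthy_LS-FMD section. Heat shock genes (5 of 8 higher, 0.63, Hsph1 1.92-fold, Hspa1b 1.76-fold) and endoplasmic reticulum stress genes (6 of 16 higher and 1 lower, 0.42, Hspa5 1.86-fold, Xbp1 1.80-fold) lay above random lists. So did nephron progenitor genes (4 of 18 higher and 1 lower, 0.46, Sox9 1.61-fold higher, Cited1 3.10-fold lower) and principal cell genes (2 of 8 higher, 0.40), which had -0.33 in medullary spots. Proximal tubule S1 and S2 genes (2 of 15 lower, -0.22, Slc5a2 1.74-fold), gluconeogenesis genes (1 of 9 lower, -0.19) and red blood cell genes (4 of 5 lower, -1.80) lay below. Against the healthy_LS-FMD section the S1 and S2 (0.86), gluconeogenesis (0.79), red blood cell (1.48), principal cell (-0.88) and nephron progenitor (-0.02) medians took the opposite direction.

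The remaining lists did not meet the rule. Among segments and cell types these were parietal epithelial (-0.06), endothelial (0.10), mesangial and smooth muscle (0.08), S3 (0.37), thick ascending limb (-0.07), distal tubule (-0.12), intercalated cell (-0.05), inner medulla (0.14), adipocyte (-0.02) and adrenal genes (1.08). Others were interferon response (0.32, Mx2 2.14-fold and Mx1 2.10-fold higher), fatty acid oxidation (-0.03, Acaa2 2.04-fold lower) and antioxidant genes (0.10, Hmox1 3.80-fold higher). The rest were complement (0.38), oxidative phosphorylation (-0.12), sterol synthesis (-0.03), insulin and IGF (0.15), cell cycle (0.08), autophagy (0.05), sodium transport (0.26), immediate early (0.09), clock (0.28), glucocorticoid (0.18) and hypoxia genes (0.15). The genes with the highest fold included Pnoc (at least 133-fold, with no UMIs in the healthy cortex), Dmrtc1c1 (49.3-fold), the MHC class II gene RT1-Bb (36.6-fold), and Zmym6nb and Vegfb (11.1-fold each). They were followed by Cldn6 (9.17-fold), the MHC class I gene RT1-T24-4 (8.56-fold), P3h3 (6.72-fold) and Gpx2 (5.42-fold). Over all spots Dmrtc1c1 and RT1-Bb were lower in the healthy section than in every other section, PAN included. Those with the lowest included Gal (96.5-fold lower), Fam111a (84.5-fold), Prcp (16.6-fold), Akr1b10 (14.6-fold) and Tmem125 (11.2-fold), then RT1-N2 (11.1-fold), Cyp4a2 (9.57-fold), Scd2 (7.15-fold) and Tspan1 (6.73-fold). Tmem125 and Cyp4a2 are symbols of several identifiers.

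The fourth comparison, healthy_LS-FMD against healthy, asked what 1 cycle of the diet and 72 h of refeeding left in a kidney without injury. In cortical spots, genes of sodium transport, distal segments and sterol synthesis were higher, while genes of the proximal tubule, of glucose production and of fatty acid oxidation were lower. The sterol regulator Srebf1 was 2.37-fold higher and the clock gene Nr1d1 3.69-fold (3.35 to 4.06). Vnn1, a pantetheinase, was 10.2-fold lower (8.81 to 12.0) and Cyp4a1, a fatty acid hydroxylase, 6.48-fold (5.32 to 7.96). All genes had a median log2 fold of 0.25, and of -0.02 by median of ratios. Without the cortical regions led by Cyp24a1, an alternative added after the data had been seen, the medians were 1.14 for sodium transport, 0.69 for sterol synthesis, -1.08 for both proximal tubule S1 and S2 and gluconeogenesis, and -0.67 for fatty acid oxidation. The regions are still not the same in both sections.

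Genes of sodium transport and its hormones were higher in 12 of 17 and lower in 1 (median 0.89, 0.69 to 1.08, against -0.09 to 0.41), with the sodium channel subunits Scnn1a 3.41-fold and Scnn1b 2.36-fold and the cotransporter Slc12a1 2.74-fold higher. Principal cell genes (8 of 8, 1.25, Aqp4 4.34-fold, Aqp2 2.40-fold) and thick ascending limb genes (5 of 8, 0.74) were higher. So were distal convoluted and connecting tubule genes (2 of 3, 1.13, Calb1 and Slc12a3 2.19-fold each) and intercalated cell genes (5 of 6, 0.83, Slc4a1 2.69-fold), which had -0.34 in medullary spots. Proximal tubule S1 and S2 genes were lower in 12 of 15 (median -0.998, -1.03 to -0.87, Slc4a4 3.74-fold, Slc5a2 3.17-fold), and in outer stripe and medullary spots their medians were -0.72 and -2.17, where regions led by Cyp24a1 were in these zones of the healthy section only. Gluconeogenesis genes were lower in 6 of 9 (median -0.998, G6pc 2.73-fold, Fbp1 2.18-fold, Pck1 2.0-fold), 5 of the 11 genes in that list being shared with other lists. Fatty acid oxidation and ketogenesis genes were lower in 9 of 24 and higher in 1 (median -0.41, -0.46 to -0.37, against -0.03 to 0.37; Angptl4 6.02-fold lower). Sterol and fatty acid synthesis genes were higher in 11 of 18 and lower in none (median 0.67, 0.58 to 0.75, against 0.07 to 0.46), with Idi1, an enzyme of isoprenoid synthesis, 2.14-fold besides Srebf1. Their medians in outer stripe and medullary spots were 0.23 and 0.98.

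Tubular injury genes had a median of -0.10 (-0.19 to -0.01), below random lists (0.02 to 0.44), and of 0.15, the opposite direction, over the section. Of 22 measured, 4 were higher (Sox9 3.12-fold, Spp1 1.89-fold and Lgals3 1.80-fold among them) and 5 lower (Fgb 2.49-fold). Macrophage genes (5 of 19 lower and 2 higher, -0.25, Lyz2 2.0-fold lower) and interferon genes (5 of 18 lower and 1 higher, -0.31, Psmb9 2.21-fold lower) were lower in cortical spots and had medians of 0.19 and 0.24 over the section. T and NK cell genes were lower in 3 of 8 (-0.51) with -0.04 over the section, and B and plasma cell genes higher in 2 of 4 (1.00, Ighm 4.22-fold, Igkc 3.45-fold). Antioxidant genes (3 of 10 higher and 2 lower, 0.43, Gpx1 2.31-fold and Gpx3 3.95-fold lower) had -0.02 over the section. Red blood cell genes were lower in 5 of 5 (-2.98) and adipocyte genes higher in 3 of 3 (0.95). Podocyte genes were higher in 4 of 18 (0.28, 0.20 to 0.41), within random lists. Under the alternatives their median ran from 0.0031 by median of ratios to 1.12 when the sections were clustered together. Nphs1 was 1.71-fold higher and Vegfa 1.78-fold, and Wt1 stood at 30.5 against 22.0 CPM. Podocyte sets A (0.15) and B (0.58) did not meet the rule, and neither did nephron progenitor (0.48, Cd24 2.06-fold higher), mesangial and smooth muscle (0.36, Acta2 2.49-fold higher), endoplasmic reticulum stress (0.32, Phgdh 4.11-fold lower) and clock genes (0.53, Dbp 2.12-fold higher). The same was so for glucocorticoid genes (0.03, Fkbp5 2.82-fold higher, Sgk1 2.30-fold lower) and for parietal epithelial (-0.23), endothelial (0.04), S3 (0.54), inner medulla (0.58), matrix (0.00), complement (0.00), oxidative phosphorylation (-0.04), insulin and IGF (0.36), cell cycle (0.06), autophagy (0.13), immediate early (0.26), heat shock (0.13) and hypoxia genes (0.40). Adrenal genes were too low to measure. In medullary spots the medians of injury (0.30), macrophage (0.29), T and NK cell (0.13), interferon (0.53) and antioxidant genes (-0.41) had the opposite sign. Without the cortical regions led by Cyp24a1 those of macrophage (0.03) and antioxidant genes (-0.02) did so too, the podocyte median was 0.79 and the injury median was -0.0022.

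The genes with the highest fold were the aldo-keto reductase Akr1c2 (458-fold, 126 to 3795, from 2 UMIs in the healthy section), Gh1 (growth hormone, at least 406-fold, from 0 UMIs), Dmrtc1c1 (81.7-fold) and RT1-Bb (34.2-fold). They were followed by the betaine transporter Slc6a12 (8.97-fold), Apoh (6.88-fold), Akr1c13 (6.25-fold), Ndrg4 (5.52-fold), Slc4a11 (5.46-fold) and Nipal1 (5.15-fold). Over all spots Dmrtc1c1 and RT1-Bb stood at 2.99 and 3.81 CPM in the healthy section and at 34.6 and 49.3 in the PAN section. They were thus higher without the diet too, and an effect of the Space Ranger version on these single genes was not tested. Those with the lowest included Ubd (55.9-fold lower), the haem synthesis gene Alas2 (12.9-fold), Vnn1, Prima1 (8.92-fold), Hrg (8.61-fold), Gal (8.48-fold), Slc7a7 (7.67-fold), Tex36 (6.82-fold) and Cyp4a1. RT1 and Akr1c genes belong to families of similar sequence, and how reads were shared among their members was not given in the sources used here.

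Glomerular spots, selected by podocyte marker set A at equal depth, made up 11.1% (9.40 to 13.1) of cortical spots in the PAN section, 20.4% (17.9 to 23.0) in the healthy section, 28.6% (25.9 to 31.4) in the PAN_LS-FMD section and 25.2% (22.4 to 28.0) in the healthy_LS-FMD section. These are shares of the 1166, 1016, 1064 and 950 cortical spots with at least 3000 UMIs. Among spots outside cortex the same selection took 11.5, 5.2, 6.09 and 8.24%, so in the PAN section the cortical share was no higher than this background. At a minimum of 3 UMIs the cortical shares were 3.26, 10.5, 15.7 and 12.2% against a background of 2.36, 0.920, 0.806 and 1.75%. With selection on set B they were 4.63, 10.4, 16.9 and 19.7% against 1.25, 1.30, 1.43 and 6.68%. Set B RNA stood at 321 (289 to 356), 525 (501 to 550), 607 (582 to 632) and 709 (670 to 750) CPM in the spots selected on set A. At the minimum of 3 UMIs it stood at 797, 879, 904 and 1197, with a PAN to healthy ratio of 0.906 (0.793 to 1.03). Set A RNA in spots selected on set B stood at 944, 1547, 1520 and 1250, with a ratio of 0.610 (0.555 to 0.671). In the spots with at least 2 UMIs of set A, tubular injury RNA summed over the list was 24353 CPM in the PAN section and 2991, 2804 and 2860 in the others. Matrix RNA was 10418 against 2656, 2953 and 2697. Since the PAN share did not exceed background, these PAN spots are not shown to be glomerular. Spp1 alone stood at 19022 CPM over the PAN cortex, and its part in the injury sum was not measured. At the minimum of 3 UMIs the injury sums were 23984.5, 3921, 3266 and 3474 CPM.

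**Figure D3:**
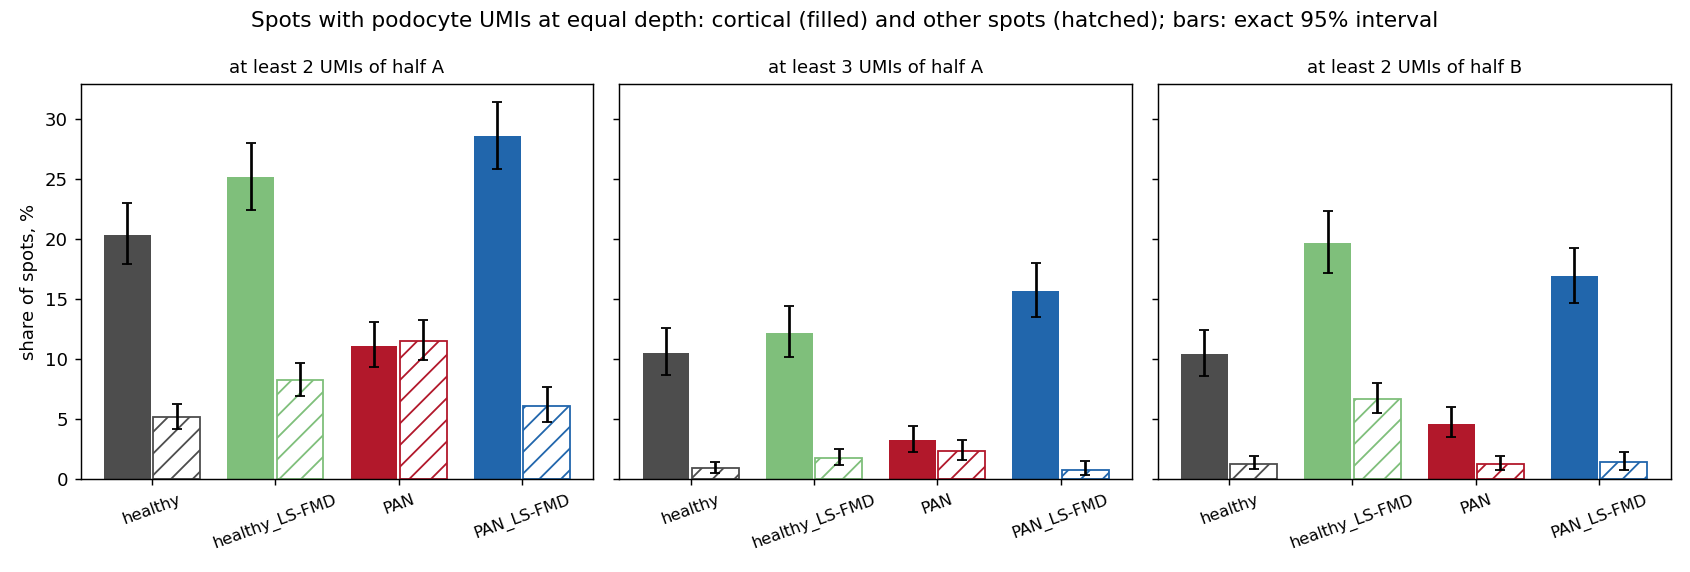
Percent of spots (vertical axis) counted as glomerular in each section among spots thinned to 3000 UMIs, for cortical spots (filled) and spots outside cortex (hatched), with exact 95% intervals; panels show at least 2 UMIs of podocyte set A, at least 3 UMIs of set A, and at least 2 UMIs of set B. The PAN section had the lowest cortical share in each panel, 11.1, 3.26 and 4.63%.

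Between the sections, the median absolute log2 difference of cortical genes was 0.513 for PAN and healthy, 0.359 for PAN and PAN_LS-FMD and 0.223 for healthy and PAN_LS-FMD. It was 0.329 for healthy and healthy_LS-FMD, 0.355 for PAN and healthy_LS-FMD, and 0.194 for the pair with the diet, over 7012 genes. These values include a shift common to all genes, a median log2 of -0.18 for healthy over PAN_LS-FMD and -0.06 for the pair with the diet. By genes at least 1.5-fold apart the order was the opposite, with 7.84% for healthy and PAN_LS-FMD and 11.3% for the pair with the diet. Over all spots the median absolute differences were 0.186 and 0.283 in that order, so which pair was most alike depends on the measure. The diet contrasts in rats with and without the injection share no section and were compared across 8018 genes. Their log2 folds had a Pearson r of 0.0115 (0.0057 to 0.0179) and a Spearman rho of -0.0841. The same sign was seen in 37.6% of genes, against 43.4% if the contrasts were independent. At least 1.5-fold higher in both were 226 genes, against 160 if independent, and 115 were at least 1.5-fold lower in both, against 68.5. Genes this far apart in opposite directions were not counted, so this excess alone does not show a shared response. Over all spots r was -0.271 and rho -0.397, and the shared genes were fewer than if independent, with 110 against 252 higher and 76 against 131 lower. Genes are not independent replicates, and the schedules differed, with 6 cycles in injected rats and 1 cycle with 72 h of refeeding in the others. The lists of sodium transport (1.08 and 0.89) and principal cells (1.39 and 1.25) were higher in both contrasts in cortical spots. In medullary spots they had -0.25 and 0.68, and -0.08 and 0.96. Synpo, Pax2 and Six2, named beforehand, had at most 5 UMIs in any cortex and allow no comparison.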

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

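Of the tests below, that of the Space Ranger version for injury genes, those of RNA of other cells and of fewer glomerular spots, and that of zone share with the PAN section left out were added only after the result had been seen. The lists below drew attention because the diet contrast had the opposite direction in injected rats (PAN_LS-FMD against PAN) and in rats without injection (healthy_LS-FMD against healthy). Proximal tubule S1 and S2 genes had a median log2 fold of 0.85 in the former and -0.998 in the latter. B and plasma cell genes had -4.40 and 1.00, gluconeogenesis genes 0.90 and -0.998, and red blood cell genes 1.61 and -2.98. The equal value of -0.998 is that of Slc2a2, the middle gene of both lists. Fatty acid oxidation genes also took opposite directions, but their median of -0.41 in rats without injection fell short of 1.5-fold. The difference between the contrasts was not tested, since each group had 1 section. The schedules also differed, with 6 cycles against 1 cycle and 72 h of refeeding, so diet, timing and animal remain open.

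Injury, matrix and immune genes were higher in the PAN section than in the healthy one. A different Space Ranger version for the healthy section is excluded as the whole cause, because against the healthy_LS-FMD section, made with the same version as PAN, the injury median was 2.30 (2.06 to 2.63). Without the 20 most abundant genes in the total it was 2.04 (1.89 to 2.18), which argues against a few genes taking a different share. The lowest median of the 3 zones, in medulla, was 1.99 (1.89 to 2.05). That argues against a different mix of the zones as assigned, though they did not hold the same regions in every section. A lasting effect of the injection may be the source, as a hypothesis raised on these sections and not itself tested, and a difference between single animals stays open.

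Podocyte genes were lower in cortical spots of the PAN section than in those of the healthy one. Over all spots the median was -0.16 (-0.32 to 0.03), and in outer stripe and medullary spots it was positive. Nphs1 was lower in the PAN section in both of these zones (2.39 against 4.96 and 2.36 against 6.30 CPM), while Wt1 and Podxl were each lower in only 1 of them. RNA of other cells diluting every resident type alike would lower the endothelial list as far. The endothelial median lay 0.62 (0.44 to 0.79, counting error only) above the podocyte median on the log2 scale, which argues against this as the whole cause. The medians of the proximal, thick ascending limb, distal, principal cell and intercalated cell lists were as low as that of podocytes or lower. Dilution of podocyte and tubule RNA together therefore stays open. With spots thinned to 3000 UMIs the podocyte median was -0.80 (-0.87 to -0.49). Random thinning keeps the expected share of each gene, and the zones were those of the full counts, so this cannot decide on lower depth. Fewer glomerular spots with unchanged podocyte RNA in each cannot be told apart from less podocyte RNA per glomerulus: the PAN to healthy ratio was 0.61 (0.55 to 0.67) in spots selected on set B, but 0.906 (0.793 to 1.03) in spots with at least 3 UMIs of set A. A biological difference, such as podocyte loss after the injection, could not be tested apart from the animal.

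Some genes were nearly on or off in 1 section of 4, that is at least 8-fold apart from all 3 others over all spots of the sections. The PAN section had 102 of them among 10071 genes, the healthy section 4 (Dmrtc1c1, Gh1, RT1-Bb and Trim50, all lower), the PAN_LS-FMD section 3 and the healthy_LS-FMD section 7. A different Space Ranger version would set the healthy section apart most, and its 4 genes against the highest count of 7 in the other non-PAN sections exclude it as the cause of the number, though not for single genes. Of the 116 cases, 83.6% (75.6 to 89.8, as if genes were independent) were at least 4-fold apart in all 3 zones, 89 of those in the PAN section. This argues against a different share of the zones as assigned as the cause of the set as a whole. It cannot exclude a regional difference, since the zones did not hold the same regions in every section. PAN cortex and outer stripe held regions whose matrix or injury scores exceeded the score that placed them. Of the 14 cases outside the PAN section, which are 13 different genes since Gh1 stood apart in 2 sections, 57.1% (28.9 to 82.3) were at least 4-fold apart in all 3 zones. These are too few cases to decide, so there a different share of a zone cannot be told apart from a difference in the tissue. No biological explanation was tested.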

How the results depend on the processing

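The comparison with the healthy_LS-FMD section as the reference, the PAN cortex without its matrix-rich cluster, the total without haemoglobin genes and the cortex without clusters led by Cyp24a1 were chosen only after the data had been seen. Of the values under the alternatives, 1341 list medians stayed within their counting interval, 664 moved beyond it and 20 took the opposite direction, which concerned 12 of 159 list medians. The opposite direction was counted only for lists that met the rule for lists in the main setting. Other medians could also change sign, as that of injury genes for PAN_LS-FMD against healthy did. Of the member counts 821 stayed within 1.5 times and 133 did not, of the named genes 783 stayed, 225 moved and 2 reversed, and of the shares 4 stayed and 32 moved. No paired analysis was possible because each group had 1 section. Unless a construction is named, the cause was not tested.

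For PAN against healthy, the podocyte median of -0.70 became -1.14 by median-of-ratios size factors (1 factor for every gene), -0.16 over all spots, -0.36 with joint clusters, -0.80 with thinned spots, -0.84 without the 20 most abundant genes, -1.04 against the healthy_LS-FMD section and -0.0091 without glomerular spots, which removed podocyte-rich spots by construction. Its 10 lower members were 5 at 2-fold. The S1 and S2 median was 0.28 against the healthy_LS-FMD section. The injury median of 2.18 became 1.73 by median of ratios and 1.99 with thinned spots.

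For PAN_LS-FMD against PAN, the podocyte median of 1.09 became 1.34 by median of ratios, 0.58 over all spots, 0.91 without glomerular spots and 0.95 without the matrix-rich cluster, and the injury median of -1.86 became -1.61, -2.09, -2.20 and -1.67 under the same 4 and -1.77 without the 20 most abundant genes. Inner medulla genes had -0.50 over all spots.

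For PAN_LS-FMD against healthy, the podocyte median of 0.49 became 0.29 by median of ratios, 0.63 with all deposited spots, 0.84 with joint clusters, 0.59 with a score per spot, 0.60 without glomerular spots, 0.72 without clusters led by Cyp24a1 and 0.19 against the healthy_LS-FMD section, and its 6 higher members were 0 at 2-fold. The injury median of 0.08 became -0.12 by median of ratios, 0.19 with all deposited spots and -0.23 over all spots, and its 3 higher members were 0 at 2-fold. B and plasma cell genes had -0.56 over all spots, where Spp1 also had -0.56. Against the healthy_LS-FMD section the direction turned for nephron progenitor (-0.0225), S1 and S2 (0.86), principal cell (-0.88), B and plasma cell (-0.0865), gluconeogenesis (0.79) and red blood cell genes (1.48).

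For healthy_LS-FMD against healthy, the podocyte median of 0.28 became 0.0031 by median of ratios, 0.59 with all deposited spots, 0.57 over all spots, 1.12 with joint clusters, 0.55 with a score per spot, 0.60 with thinned spots and 0.79 without clusters led by Cyp24a1, and its 4 higher members were 0 at 2-fold. The injury median of -0.10 became -0.37 by median of ratios and -0.0022 without clusters led by Cyp24a1, and reversed to 0.15 over all spots, 0.10 with joint clusters and 0.14 with a score per spot. At 2-fold, 1 injury gene was higher and 1 lower, against 4 and 5. Macrophage (0.19 and 0.0506) and interferon genes (0.24 and 0.16) reversed over all spots and with a score per spot, and antioxidant genes over all spots (-0.0217) and with joint clusters (-0.30). Without clusters led by Cyp24a1 macrophage (0.0348) and antioxidant genes (-0.015) reversed too. Podxl turned to -0.0111 by median of ratios.

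The glomerular shares of 11.1, 20.4, 28.6 and 25.2% in the PAN, healthy, PAN_LS-FMD and healthy_LS-FMD sections became 3.26, 10.5, 15.7 and 12.2% at 3 UMIs, 4.63, 10.4, 16.9 and 19.7% with selection on set B, and 42.3, 79.8, 82.0 and 58.3% without thinning, where deeper spots pass more readily by construction. The cortex shares were 50.8, 38.3, 57.5 and 44.2% at a resolution of 0.5, and 46.0% in the PAN_LS-FMD and 32.7% in the healthy_LS-FMD section at a resolution of 2. The correlation of the diet contrasts was -0.271 over all spots. Depth limits genes near 3 counts, worth 0.165 to 0.339 CPM in cortex.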

Other observations

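The genes of single sections were chosen after their values were seen. Over all spots of the PAN_LS-FMD section Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, stood at 16.0 CPM against 0.321, 1.06 and 1.58 in the other sections, and was at least 4-fold apart from them in 2 of 3 zones. Over all spots of the healthy_LS-FMD section Akr1c2 stood at 85.0 and Gh1 at 53.4 CPM, with Scgb1a1 and Gucy2g also far above the other 3 sections, and Ubd at 0.868 against 219, 29.1 and 26.1. Kap stood at 483 CPM in the PAN cortex against 8481, 8552 and 11185 in the healthy, PAN_LS-FMD and healthy_LS-FMD cortex, and at 4572 against 26066, 26234 and 22235 in outer stripe spots. Spp1 stood at 15605, 757, 238 and 3204 CPM in medullary spots of the PAN, healthy, PAN_LS-FMD and healthy_LS-FMD sections, so its level outside cortex also differed between the sections without injection. Of the Y-linked genes, Usp9y had 53 UMIs in the healthy_LS-FMD section and 0 in the others.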
